A study of Homo sapiens with 12 samples.

How the data were processed

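The data are RNA-seq gene counts from 12 MCF-7 libraries in 6 groups of 2, given by 3 kinds of cell (vector, wild-type ER, dDBD ER) and 2 treatments (100 nM estradiol for 6 h, or ethanol). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded mRNA kit, the ER constructs were delivered by lentivirus and the hairpins by a transient infection. The authors deposited a table of whole-number counts per gene, which are not normalized. Per the submitters' processing notes, CASAVA, STAR 2.5.2b, featureCounts and DESeq2 were used with the hg19 genome. The gene annotation, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Antisense and overlapping genes, and close paralogs such as KRT6A, KRT6B and KRT6C, S100 genes and the alpha-globin genes, are therefore reported as uncertain. No coordinates are given, because the reference at hand is another build and served only for gene symbols, transcript GC content and length, which 95.2% of the tested genes had.

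The table held 27140 genes, of which 5042 had no count in any library. Totals ranged from 7964109 to 13138427 counts per library, so that 3 counts corresponded to 0.228 to 0.377 CPM. Library factors were computed with the TMM method and genes were kept by edgeR's filterByExpr on the 6 groups, which left 14216. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) was fitted once to all 12 libraries with 1 mean per group, since 2 libraries per group are too few to estimate the spread alone. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 5.27%. Within groups the chi-square of replicate counts per degree of freedom lay between 1.73 and 3.82, above the value of 1 that counting error alone gives, so no pair of libraries was treated as 1 sample.

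The contrasts were E2 against vehicle in each kind of cell, the 3 differences between those responses tested as interaction terms, and the 3 differences between kinds of cell in vehicle. Genes called in vector cells were then followed as sets in the other cells with fry. For 21 gene lists, camera with a preset correlation between genes of 0.01 was run in each contrast, again with the correlation estimated, and with fry, with adjustment over the lists of a contrast. The lists cover estrogen-induced and estrogen-repressed genes, G1/S, mitosis, ribosome biogenesis, cholesterol synthesis, the unfolded protein response, immediate early, TGF-beta and mesenchymal, luminal identity, ER cofactor, interferon, p53, apoptosis, NF-kB and hypoxia genes, core histones, and markers of fibroblasts, leukocytes and virus-packaging cells. A list needed 5 tested members. The list of mitochondrially encoded genes had 0 and was not analysed here. Of the 49 list calls at the preset correlation, 16 held with the estimated one.

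The contrasts, the lists and the rule for named genes were fixed before the data were examined. The rule names ESR1, GREB1, PGR, TFF1, TM4SF1 and EFEMP1 in each E2 contrast. It adds the 8 genes with the largest change in each direction among those called, with a mean of at least 2 CPM and both replicates of one group above both of the other, and up to 4 members with the lowest p of each list described. Fewer are printed than it names. In the closing list of differences, 4 genes per direction are given, and genes with 3 or fewer counts summed over a compared group were passed over, a step added after KRT1 had been seen there. Levels of further keratin and squamous genes, and of AGR2 and H19 outside its rule, were looked up after the data were seen.

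Alternatives fixed beforehand were a replicate block, DESeq2 size factors, no filter on low counts, a minimum of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, fits of only the 4 libraries of a construct, the other set tests, and leaving out each library. Leaving out a library leaves its group with 1 library, which is assumed to vary like the other groups. Other alternatives were added after seeing the data. One refit without the wild-type ER libraries followed the ESR1 levels seen there. The other was a correction of each library for GC content and transcript length by splines with 5 and 4 degrees of freedom, entered as offsets. Its first version, centred on the fitted curve, moved the median fold change in vector cells from -0.026 to -0.063, so the version that keeps each library's median (-0.028) is the one quoted unless stated, and the counts of genes are given for both.

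The test was tried on simulated counts drawn from the real means, library sizes and spread, with 200 changed genes. For the contrast of E2 in vector cells, over 14080 genes, it recovered 64.2% of 1.5-fold, 83.6% of 2-fold and 90.9% of 4-fold changes, with 10 calls among unchanged genes. For a difference of responses it recovered 43.3%, 68.7% and 83.3%. A raised set of 40 genes was recovered, and of 20 random sets 0 passed camera and 2 passed fry, so a fry result alone is weak evidence. With a GC and length bias as large as in the real libraries and no correction, 1739 unchanged genes (12.4%) of 14030 were called, and 12 after the correction. That bias was simulated from the curves the same correction had fitted, so its removal was built in. The changed genes were drawn without regard to GC content. The simulation therefore cannot show whether the correction separates bias from an E2 effect that follows GC content. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.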

Results

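RNA was sequenced from MCF-7, a human breast cancer cell line that expresses the estrogen receptor (ER, gene ESR1), a transcription factor activated by estradiol (E2). Vector cells carried a control short hairpin RNA. Wild-type ER cells and dDBD ER cells carried an introduced form of the receptor together with a hairpin directed at the 3′ untranslated region of the cells' own ER transcript. The name dDBD is used as the labels give it. Each kind of cell was kept without hormone for at least 3 days and then given 100 nM E2 or ethanol vehicle for 6 h, with 2 libraries per condition and 12 in all. The series title names estrogen-induced repression and ER at enhancers, so the comparisons ask which transcripts E2 raised and lowered and how that differed with the form of the receptor.

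Gene counts summed to 8128163 and 11569988 in the vector vehicle libraries, 13138427 and 8345995 in vector E2, 9166427 and 8603788 in wild-type ER vehicle and 7964109 and 8077759 in wild-type ER E2. The dDBD ER vehicle libraries held 8540144 and 8932622 counts and the dDBD ER E2 libraries 12925718 and 10001927. Levels are given in CPM, the count of a gene scaled to the size of its library, as mean ± SD of 2 libraries, and fold changes are on the log2 scale. The labels do not say that the 2 libraries of a condition came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

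ESR1, the gene targeted by the hairpin and carried by the constructs, differed between the cell types. Its level was 148 and 146 CPM in the vector vehicle libraries, 312 and 285 in wild-type ER vehicle and 397 and 429.9 in dDBD ER vehicle. With E2 it was 94.7 and 108 CPM in vector cells, 103 and 102 in the libraries labelled wild-type ER, and 410.4 and 416 in dDBD ER cells. Counts per gene do not separate the cells' own ESR1 from the introduced one, so the knockdown itself was not measured. In vehicle, ESR1 was higher than in vector cells by 1.02 (SE 0.072, adjusted p = 2.51e-12) in wild-type ER cells and by 1.49 (SE 0.072, adjusted p = 1.79e-16) in dDBD ER cells. E2 lowered it in vector cells by -0.54 (SE 0.076, adjusted p = 1.14e-06) and in wild-type ER cells by -1.55 (SE 0.076, adjusted p = 1.34e-16). In dDBD ER cells its change did not pass the test (-0.0020, SE 0.068, adjusted p = 0.991), and the sign of that value turned with the scaling (0.015 with DESeq2 size factors), with the correction for GC content (0.083) and without dDBD ER vehicle replicate 2 (0.057).

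**Figure D1:**
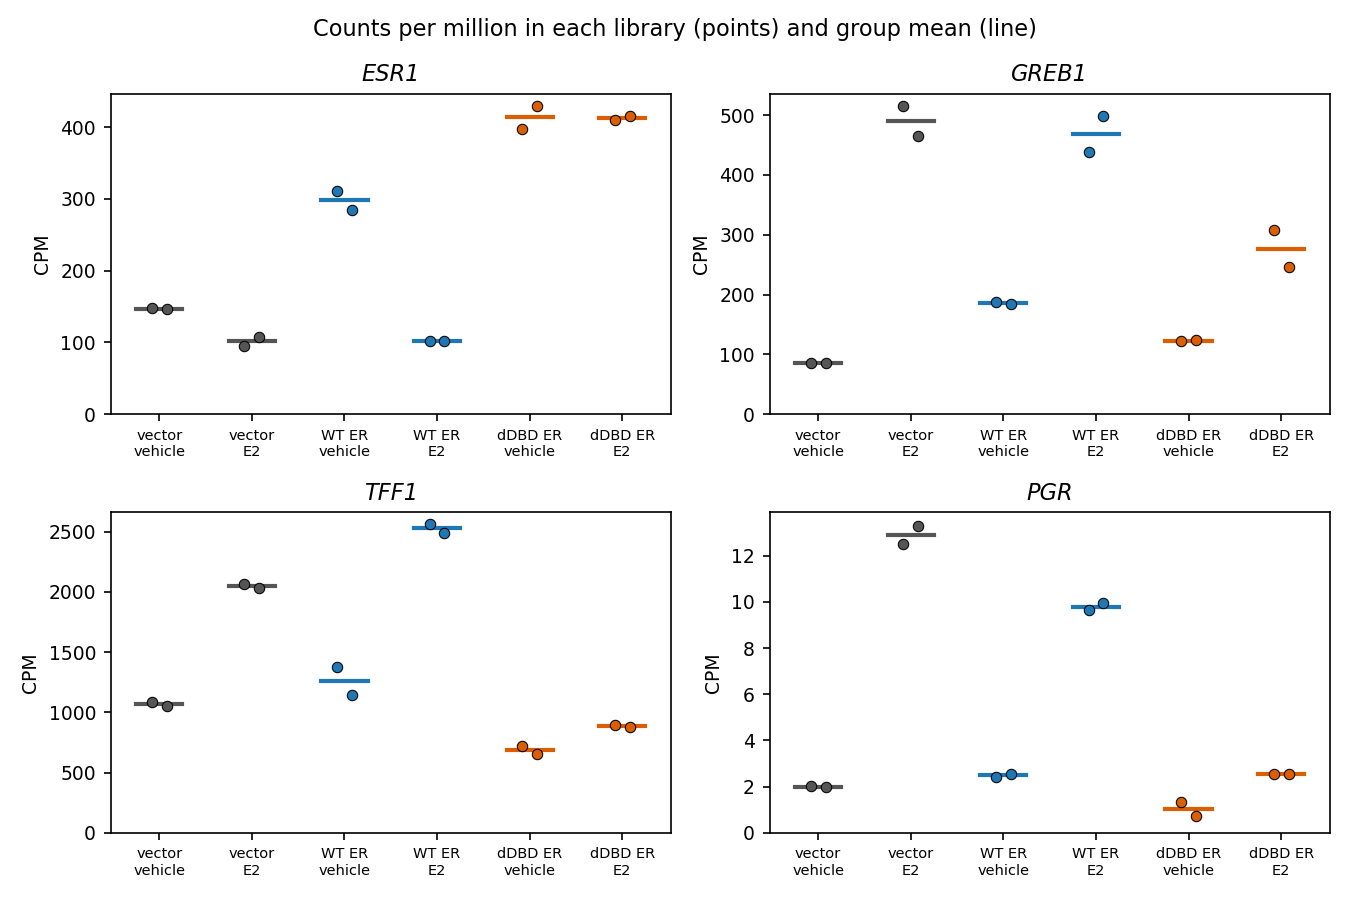
Points give the CPM of ESR1, GREB1, TFF1 and PGR in each of the 12 libraries and lines give the mean of the 2 libraries of a condition, on linear axes that start at 0. GREB1, TFF1 and PGR lie higher with E2 than with vehicle in each kind of cell, while ESR1 falls with E2 to 101 CPM in vector and 102 CPM in wild-type ER libraries and stays at 413 CPM in dDBD ER libraries.

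In vector cells, 6 h of E2 raised classical ER targets and lowered a comparable number of genes. GREB1, an early ER target, rose from 85.5 ± 0.874 to 490.0 ± 34.7 CPM, and the progesterone receptor gene PGR rose from 1.99 ± 0.0302 to 12.9 ± 0.546 CPM. TFF1, a secreted trefoil peptide, rose from 1066 ± 24.7 to 2050.3 ± 25.1 CPM. The largest rises among the named genes were those of the long non-coding RNA LINC01016 (4.54, SE 0.27, adjusted p = 2.02e-14), ANKRD2 (3.77), the zinc-finger factor EGR3 (3.54), the adenosine receptor ADORA1 (3.46) and the Src-family kinase HCK (2.98). Among the largest falls were TNFRSF11B, which encodes osteoprotegerin (-2.27, SE 0.30, adjusted p = 5.60e-07), HCAR1 (-2.17), the immune checkpoint ligand VTCN1 (-2.05, SE 0.16, adjusted p = 1.25e-11), CDKL5 (-1.98) and the copper transporter ATP7A (-1.87). EFEMP1, an extracellular matrix protein, fell from 13.5 ± 2.85 to 7.03 ± 0.416 CPM (-0.97, adjusted p = 4.68e-05). TM4SF1 was below the count minimum, with 3 and 5 counts in the vehicle and 8 and 2 in the E2 libraries.

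The estrogen-induced list moved most in vector cells. Of its 60 members 49 rose and 1 fell (50 and 2 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 2.01e-49). RAPGEFL1 (2.09), the growth-factor binding protein IGFBP4 (1.83) and the retinoic acid receptor RARA (1.54) were among them. Of 38 estrogen-repressed genes 25 fell and 5 rose, with the same numbers adjusted over the list alone and a median of -0.51 (adjusted p = 4.16e-08). The pro-apoptotic gene BMF (-1.76), the monooxygenase CYP1A1 (-1.45) and the transcriptional inhibitor ID3 (-0.89) fell, whereas the semaphorin SEMA3B rose from 69.7 ± 1.62 to 197 ± 11.7 CPM. Ribosome biogenesis genes rose, 28 of 40 against 1 that fell (28 and 2 adjusted over the list alone, median 0.56, adjusted p = 7.82e-20), including the assembly factors PPAN (1.29), BOP1 (1.02) and RRP12 (0.89). Genes of the G1/S transition and DNA replication rose in 24 of 44 cases and fell in 4 (25 and 4 adjusted over the list alone, median 0.33, adjusted p = 0.000232), among them the licensing factor CDT1 (0.84), the transcription factor E2F1 (0.83) and the helicase subunit MCM7 (0.66). The G1/S call was lost when the correlation between genes was estimated (adjusted p = 0.0922 with an estimated correlation). Mitotic genes fell in 14 of 30 cases and rose in 2, with the same numbers adjusted over the list alone (median -0.35, adjusted p = 0.00134), with the mitotic kinesins KIF23 (-0.77) and KIF20A (-0.76) among those that fell. Their adjusted p was 0.381 with an estimated correlation.

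Other lists did not pass in vector cells. Luminal identity genes had a median of -0.097 with 9 of 25 up and 8 down (10 and 11 adjusted over the list alone, camera adjusted p = 0.696), and ER cofactors a median of -0.027 with 10 of 40 up and 14 down (10 and 15 adjusted over the list alone, adjusted p = 0.375). In both lists the pioneer factor FOXA1 fell (-0.77). Cholesterol synthesis genes split 7 up and 8 down of 24, alike over the list alone (median -0.16, adjusted p = 0.920), and apoptosis regulators 3 up and 8 down of 22, alike over the list alone (median -0.17, adjusted p = 0.0886). Unfolded protein response, immediate early, TGF-beta and mesenchymal, interferon, NF-kB and hypoxia genes gave adjusted p between 0.303 and 0.920, and p53 targets 0.053. Marker lists for cells other than MCF-7 and the core histones did not pass either. These tests cannot show whether such cells were present, since an equal share in both treatments gives no change. Of the fibroblast markers, 5 were measurable (median -0.45, adjusted p = 0.720), of the leukocyte markers 7 (median 0.038, adjusted p = 0.689), of the markers of virus-packaging cells 5 (median -0.26, adjusted p = 0.619) and of the core histones 12 (median -0.11, adjusted p = 0.375).

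Over the 14216 genes tested, E2 raised 2930 and lowered 2684 in vector cells. Fold changes rose with transcript GC content, with a median of -0.31 in the 10% of genes lowest in GC and 0.34 in the 10% highest (Spearman's rho 0.477 across genes, which are not independent replicates). With a correction for GC content and length that kept each library's median, 2484 rose and 2556 fell (49.3% up in place of 52.2%), and with the correction centred on the fitted curve 2150 rose and 2972 fell (42.0% up). Of the genes called on the uncorrected counts, 1850 raised and 1728 lowered genes were also called after the first correction. Without vector E2 replicate 1, 1950 rose and 1608 fell, and without vector vehicle replicate 2, 1648 fell.

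**Figure D2:**
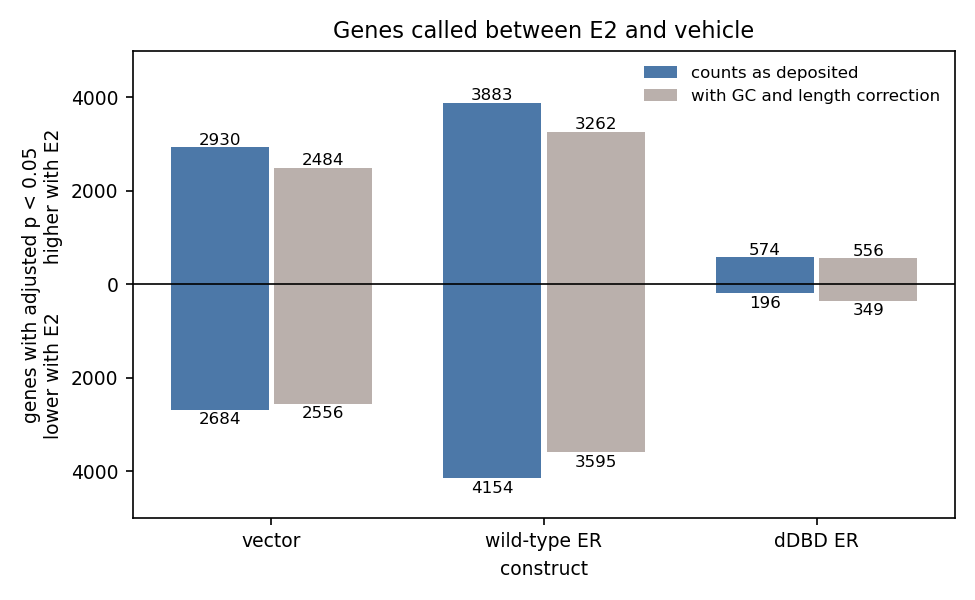
Bars give the number of genes with an adjusted p under 0.05 that were higher (above the axis) or lower (below it) with E2 than with vehicle in each kind of cell, on the deposited counts and with the correction for GC content and length. Vector and wild-type ER cells have 2930 and 3883 raised genes and dDBD ER cells 574.

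In wild-type ER cells E2 raised many ER targets and lowered ESR1. GREB1 rose from 187 ± 2.14 to 468 ± 42.9 CPM (1.33, SE 0.083, adjusted p = 2.04e-14), PGR from 2.49 ± 0.105 to 9.79 ± 0.198 CPM (1.97) and TFF1 from 1261 ± 166 to 2527 ± 57.6 CPM. ADORA1 (3.11), ANKRD2 (2.78), the receptor-modifying protein RAMP3 (2.52, SE 0.11, adjusted p = 9.27e-18), the potassium channel subunit KCNF1 (2.46) and LINC01016 (2.38) rose most, with HBA1 (2.83), whose reads can be shared with its near-identical copy HBA2, uncertain. MIR503HG (2.16) is uncertain because overlapping genes cannot be separated without the strand setting. The adhesion genes CEACAM5 (-2.72, SE 0.12, adjusted p = 7.37e-18) and CEACAM6 (-2.47), the desmosomal cadherin DSC2 (-2.68), the glycoprotein GPNMB (-2.93) and the glycosyltransferase C1GALT1 (-2.52) fell. KRT6A, a keratin of wounded epithelium with close paralogs, fell from 131 ± 32.0 to 17.3 ± 0.792 CPM (-2.92, SE 0.13, adjusted p = 1.83e-17). KRT16 did not pass (-0.078, adjusted p = 0.564), but fell after the GC and length correction (-0.64). EFEMP1 fell from 17.4 ± 0.685 to 6.43 ± 0.989 CPM (-1.44).

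Several genes that differed between wild-type ER and vector cells in vehicle had levels near those of vector cells in the libraries labelled wild-type ER, E2. The glycolytic enzyme gene PGK1 was at 2547 ± 20.9 CPM in vector vehicle, 1307 ± 85.2 in wild-type ER vehicle and 2310.3 ± 9.92 in wild-type ER E2, and TMED3 at 274 ± 0.632, 152 ± 4.09 and 316 ± 4.84 CPM. ESR1 shared this pattern, at 102 ± 0.790 CPM in wild-type ER E2 against 101 ± 9.43 in vector E2. Directions in wild-type ER cells are given with this limit, since E2 and any difference between these cultures move together.

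Among the lists, 38 of 60 estrogen-induced genes rose in wild-type ER cells and 5 fell (39 and 7 adjusted over the list alone, median 0.54, adjusted p = 7.83e-13), led by IGFBP4 (1.89), RAPGEFL1 (1.85), RARA (1.68) and the chaperone FKBP4 (1.24). Of 38 estrogen-repressed genes 23 fell and 6 rose, alike over the list alone (median -0.47, adjusted p = 6.51e-05), including CYP1A1 (-1.90) and BMF (-1.85), while the transcription factor SOX4 rose (1.26). Ribosome biogenesis genes rose in 26 of 40 cases and fell in 3, alike over the list alone (median 0.85, adjusted p = 9.78e-13), with PPAN (1.79), BOP1 (1.48) and FBL (1.10) among them. Mitotic genes fell in 21 of 30 cases and rose in 5, alike over the list alone (median -0.58, adjusted p = 0.00489), KIF23 by -1.37. This call ended with an estimated correlation (adjusted p = 0.397 with an estimated correlation) and with either GC correction (adjusted p = 0.123 and 0.0933). Of 28 p53 targets 17 fell and 6 rose, alike over the list alone (median -0.47, adjusted p = 0.0285), among them CCNG1 (-2.08), MDM2 (-1.36) and BTG2 (-1.11). The p53 list had an adjusted p of 0.115 with an estimated correlation and 0.054 without wild-type ER vehicle replicate 1.

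E2 raised 3883 and lowered 4154 genes in wild-type ER cells. The trend with GC content was steeper than in vector cells, from a median of -0.68 in the lowest 10% to 0.56 in the highest (rho 0.548 across genes). With the GC and length correction 3262 rose and 3595 fell, of which 2441 and 2626 were also called without it, and centred on the fitted curve 2865 rose and 4069 fell (41.3% up in place of 48.3%).

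In dDBD ER cells fewer genes passed, and 563 of the 574 that rose had also risen in vector cells. GREB1 rose from 123 ± 0.975 to 277 ± 43.4 CPM (1.18, SE 0.085, adjusted p = 1.08e-10) and RAMP3 from 7.77 ± 0.676 to 16.8 ± 2.88 CPM (1.10, adjusted p = 4.38e-05). PGR rose from 1.04 ± 0.422 to 2.55 ± 0.0189 CPM (1.30, adjusted p = 0.0237), a call lost without dDBD ER vehicle replicate 2 (0.93), E2 replicate 1 (1.29) or E2 replicate 2 (1.29). TFF1 rose by 0.36 (SE 0.076, adjusted p = 0.00485), which was lost without vehicle replicate 2 (0.29). The Notch-pathway factor HEY2 rose by 1.40 (adjusted p = 0.00335), lost without vehicle replicate 2 (1.03) or E2 replicate 1 (1.07), and EGR3 by 1.35 (adjusted p = 0.00662), lost without vehicle replicate 1 (1.26) or 2 (1.45). Of the lowered genes, the glycogen branching enzyme gene GBE1 fell by -1.01 (adjusted p = 0.0122), a call lost without vehicle replicate 1 (-0.94) or 2 (-1.07) or E2 replicate 1 (-0.92). EFEMP1 did not pass (-0.15, SE 0.14, adjusted p = 0.641).

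Of the estrogen-induced list 22 of 60 rose in dDBD ER cells and 0 fell (28 and 0 adjusted over the list alone, median 0.27, adjusted p = 2.70e-22), among them the glycoprotein hormone gene STC2 (0.83), IGFBP4 (0.69) and RARA (0.60). Of the estrogen-repressed list 6 of 38 fell and 1 rose (13 and 3 adjusted over the list alone, median -0.17, adjusted p = 1.59e-06), with BMF (-0.71) and ID3 (-0.50) among those that fell. Ribosome biogenesis genes rose in 16 of 40 cases (21 adjusted over the list alone, median 0.23, adjusted p = 2.37e-11), RRP12 by 0.42, and G1/S genes in 5 of 44 (7 up and 1 down adjusted over the list alone, median 0.16, adjusted p = 6.60e-05). Of 32 interferon genes 3 rose (4 adjusted over the list alone, median 0.17, adjusted p = 0.000499). These 3 were ISG15 (0.43), BST2 (0.34) and IFITM3 (0.30), and each lost its call without dDBD ER vehicle replicate 2 (0.38, 0.26 and 0.23), as IFITM3 did without E2 replicate 2 (0.29). The ribosome, G1/S and interferon lists each had adjusted p = 0.0545 with an estimated correlation.

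In dDBD ER cells 574 genes rose and 196 fell, with medians of -0.049 and 0.13 in the 10% of genes lowest and highest in GC content (rho 0.248 across genes). With the GC and length correction 556 rose and 349 fell (61.4% up in place of 74.5%), and centred on the fitted curve 396 rose and 369 fell (51.8% up). The counts rested on single libraries. Genes raised numbered 175 without vehicle replicate 1, 27 without vehicle replicate 2, 209 without E2 replicate 1 and 269 without E2 replicate 2. Genes lowered numbered 44 and 3 without vehicle replicates 1 and 2, 107 without E2 replicate 2, and 129 and 128 without vector vehicle replicates 1 and 2, which enter through the shared estimate of the spread. Without all wild-type ER libraries 310 genes fell.

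Genes called in vector cells moved the same way in the separate libraries of the other cells. The 2930 genes raised in vector cells had a median of 0.64 in wild-type ER cells, where 2540 were called raised and 23 lowered (fry adjusted p = 1.31e-06). In dDBD ER cells their median was 0.18, which is 28.7% of the wild-type ER value, with 563 called raised and 2 lowered (fry adjusted p = 0.00215). The 2684 genes lowered in vector cells had medians of -0.72 in wild-type ER and -0.16 in dDBD ER cells, the latter 22.5% of the former, with 2253 and 168 called lowered. Fry tests whether a set's genes move on balance in 1 direction and does not compare the set with other genes. Seen from the dDBD ER side, 563 of the 574 raised and 168 of the 196 lowered genes were also vector calls, where independent lists would share 118 and 37. Independence is a low bar here, since fold changes rose with GC content in both kinds of cell. With the GC and length correction, 521 of the 556 raised and 288 of the 349 lowered genes in dDBD ER cells were also vector calls. The corrected dDBD ER medians were 30.4% and 26.0% of the wild-type ER ones.

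The difference of E2 response between wild-type ER and dDBD ER cells, tested directly, was wide. Ahead in wild-type ER cells were the transporter gene SLC47A1 (2.14, SE 0.51, adjusted p = 0.00158), the potassium channel genes KCNAB3 (1.99) and KCNF1 (1.92), and within the estrogen-induced list WISP2 (1.54), IGFBP4 (1.20) and RARA (1.08). Lower there were CEACAM5 (-2.53, SE 0.16, adjusted p = 8.70e-13), CEACAM6 (-2.41), RAB27B (-2.57), GPNMB (-2.61), DSC2 (-2.60), C1GALT1 (-3.01) and ESR1 (-1.54). Of these, CEACAM5, CEACAM6, GPNMB, DSC2 and ESR1 were higher in wild-type ER than in vector cells in vehicle and near vector with E2. WISP2 was lower in wild-type ER than in vector vehicle cells (-0.98) and came nearer vector with E2. Its summed counts, in libraries of unequal size, were 651 against 1408 in vehicle and 1378 against 2135 with E2. The limit given above for such genes applies to WISP2 and to these other genes. TFF1 responded more in wild-type ER cells (0.64, and 0.24 with the GC and length correction), whereas the difference did not pass for GREB1 (0.15, SE 0.12, adjusted p = 0.337) or PGR (0.68, SE 0.46, adjusted p = 0.264). The E2 fold change, with its sign, was higher in wild-type ER cells for 2384 genes and lower, which can be a stronger fall, for 2252. With the GC and length correction these were 1778 and 1798, and centred on the fitted curve 1526 and 2048 (42.7% higher in place of 51.4%).

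Of 60 estrogen-induced genes 22 lay higher and 6 lower in wild-type ER than in dDBD ER cells, alike over the list alone (median 0.29, adjusted p = 2.95e-05), and of 38 estrogen-repressed genes 17 lay lower and 5 higher (19 and 5 adjusted over the list alone, median -0.29, adjusted p = 0.00102). With an estimated correlation these adjusted p were 0.161 and 0.0984. Ribosome biogenesis genes lay higher in 22 of 40 cases (22 and 1 down adjusted over the list alone, median 0.56, adjusted p = 5.91e-09), PPAN by 1.47. Of 28 p53 targets 11 lay lower and 4 higher (13 and 4 adjusted over the list alone, median -0.36, adjusted p = 0.00497), CCNG1 by -1.93. Both had adjusted p = 0.0984 with an estimated correlation. Of 30 mitotic genes 15 lay lower and 1 higher (17 and 3 adjusted over the list alone, median -0.47, adjusted p = 0.00130), KIF23 by -1.07. The mitotic call ended with an estimated correlation (adjusted p = 0.413 with an estimated correlation) and with either GC correction (adjusted p = 0.0672 and 0.0506).

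Against vector cells, the E2 fold change of wild-type ER cells, with its sign, was lower for PLAT, the tissue plasminogen activator gene (-4.05, SE 0.51, adjusted p = 4.49e-06), KRT6A (-3.51), DSC2 (-2.61), the kinase gene SGK1 (-2.32), LINC01016 (-2.15) and GREB1 (-1.19). It was higher for DGCR6 (1.11, SE 0.25, adjusted p = 0.00397), WISP2 (0.85) and TFF3 (0.81). Vehicle levels enter these differences, and may enter the list counts below. GREB1 went from 85.5 to 490.0 CPM in vector and from 187 to 468 CPM in wild-type ER cells. Summed counts of PLAT went from 9 to 48 and from 201 to 49, of SGK1 from 12 to 51 and from 72 to 47, and of LINC01016 from 16 to 364 and from 66 to 261. Of 60 estrogen-induced genes 17 lay lower and 3 higher (19 and 3 adjusted over the list alone, median -0.25, camera adjusted p = 1.28e-05, and adjusted p = 0.268 with an estimated correlation). Of 18 NF-kB genes 1, the cytokine gene LIF (-0.95), lay lower (3 adjusted over the list alone, median -0.31, adjusted p = 0.0108). The NF-kB list had adjusted p = 0.268 with an estimated correlation and 0.173 without wild-type ER vehicle replicate 1. ESR1 went from 147 to 101 CPM in vector and from 298 to 102 CPM in wild-type ER cells. A lower fold change can be a stronger fall, as for ESR1 (-1.55 in wild-type ER and -0.54 in vector cells). With this limit, genes with a higher or lower E2 fold change in wild-type ER cells are called responding more or less here. In all 915 genes responded more and 520 less in this sense (63.8% more). With the GC and length correction these were 794 and 624 (56.0% more), and centred on the fitted curve 633 and 667 (48.7% more). Genes responding more numbered 504 and 531 without vector vehicle replicates 1 and 2, 468 without vector E2 replicate 2, 540 without wild-type ER vehicle replicate 2 and 586 without wild-type ER E2 replicate 1. Genes responding less numbered 268 and 288 without vector vehicle replicates 1 and 2, 253 without vector E2 replicate 2 and 336 without wild-type ER vehicle replicate 2.

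The E2 response of dDBD ER cells was smaller than that of vector cells at most estrogen-regulated genes that differed. LINC01016 (-3.38, SE 0.63, adjusted p = 0.00103), EGR3 (-2.19), RAPGEFL1 (-1.55), the receptor kinase gene RET (-1.37), GREB1 (-1.34) and IGFBP4 (-1.14) responded less. The polysialyltransferase gene ST8SIA4 (1.85, SE 0.26, adjusted p = 2.35e-05), which fell with E2 in vector cells from 16.5 ± 0.513 to 4.53 ± 0.0196 CPM, lay higher, as did ESR1 (0.54). TNFRSF11B lay higher by 1.95, a call lost without vector E2 replicate 1 (1.55). Of 60 estrogen-induced genes 29 lay lower and 1 higher (36 and 1 adjusted over the list alone, median -0.57, adjusted p = 2.46e-36), and of 38 estrogen-repressed genes 14 lay higher and 2 lower (20 and 5 adjusted over the list alone, median 0.38, adjusted p = 3.88e-06), CYP1A1 by 1.12 and BMF by 1.05. Ribosome biogenesis genes lay lower in 14 of 40 cases (22 adjusted over the list alone, median -0.33, adjusted p = 3.80e-14), PPAN by -0.97. Of 28 p53 targets 4 lay higher (8 up and 1 down adjusted over the list alone, median 0.22, adjusted p = 0.0108, and adjusted p = 0.0741 with an estimated correlation), among them BTG2 (0.87) and PLK2 (0.60). G1/S genes lay lower in 3 of 44 cases (4 adjusted over the list alone, median -0.18, adjusted p = 0.0130, and adjusted p = 0.210 with an estimated correlation). Mitotic genes lay higher in 3 of 30 cases, alike over the list alone (median 0.29, adjusted p = 0.000299), with an adjusted p of 0.247 with an estimated correlation and 0.0652 by fry.

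In all 411 genes had a higher and 473 a lower E2 fold change, with its sign, in dDBD ER than in vector cells. With the GC and length correction these were 528 and 612, and centred on the fitted curve 587 and 496 (54.2% higher in place of 46.5%), so which direction held more genes depended on the correction. These counts moved with most of the 8 libraries they use. The higher ones numbered 200 and 122 without vector vehicle replicates 1 and 2, 107 without vector E2 replicate 1, 150 and 180 without dDBD ER vehicle replicates 1 and 2, and 670 and 201 without dDBD ER E2 replicates 1 and 2. The lower ones numbered 255 and 175 without vector vehicle replicates 1 and 2, 184 without vector E2 replicate 1, 203 and 255 without dDBD ER vehicle replicates 1 and 2, and 284 without dDBD ER E2 replicate 2.

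Without E2, the genes raised most in wild-type ER against vector cells included keratins and S100 genes. S100A7, the psoriasin gene, was at 0.670 ± 0.445 CPM in vector and 191 ± 44.0 CPM in wild-type ER vehicle libraries (8.02, SE 0.21, adjusted p = 6.61e-24), and S100A8, a calprotectin subunit gene, at 3.78 ± 0.350 and 207 ± 44.0 CPM (5.79). KRT6A was higher by 7.14 and KRT6B by 7.68, and KRT6C, with 0 counts in vector vehicle against 1179, was at least 429-fold higher against a floor of 3 counts over the group. These keratins are paralogs whose reads may be shared, so the split between them is uncertain. The cornified-envelope gene IVL had 3 counts in vector vehicle and 227 in wild-type ER vehicle, a ratio of 82.6 (95% interval 27.9 to 403), and S100A12 had 2 and 171, a ratio of 93.3 (25.4 to 776). These intervals and floors cover counting error only. Lower in wild-type ER cells were the ER target WISP2 (-0.98), TMEM25 (-1.01) and C6orf226 (-0.97). CD8A fell by -1.27 (adjusted p = 0.00593), a call lost without vector vehicle replicate 2 (-1.25).

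Lists that passed here were higher in wild-type ER cells unless stated. Of 60 estrogen-induced genes 25 were higher and 7 lower (29 and 8 adjusted over the list alone, median 0.26, adjusted p = 5.46e-07), GREB1 by 1.13 and KRT13 by 1.46. Of 18 NF-kB genes 9 were higher (10 adjusted over the list alone, median 0.37, adjusted p = 0.000147), LIF by 1.01 and NFKBIA by 0.35. Of 18 TGF-beta and mesenchymal genes 5 were higher (6 and 1 down adjusted over the list alone, median 0.17, adjusted p = 0.000282), KRT17 by 2.26 and the fibronectin gene FN1 by 0.82. KRT17 is a keratin that is also among the squamous genes gathered after the data were seen. Of 28 p53 targets 7 were higher and 1 lower (9 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.00317). Of 38 estrogen-repressed genes 8 were higher and 4 lower (11 and 5 adjusted over the list alone, median 0.063, adjusted p = 0.00626), CEACAM6 by 2.31. That call also ended with no filter on low counts (adjusted p = 0.0534). Each of these 5 lists had adjusted p = 0.0705 with an estimated correlation. Immediate early genes were higher in 6 of 23 cases and lower in 1 (8 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.00626), with adjusted p = 0.299 with an estimated correlation and 0.140 without wild-type ER vehicle replicate 1. Unfolded protein response genes were higher in 5 of 25 and lower in 1 (6 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0236), with adjusted p = 0.485 with an estimated correlation and 0.295 without that same library. G1/S genes were higher in 4 of 44, alike over the list alone (median 0.15, adjusted p = 0.0391), with adjusted p = 0.260 with an estimated correlation, 0.284 without that library and 0.0613 without vector vehicle replicate 1. Ribosome biogenesis genes were lower in 9 of 40 (10 adjusted over the list alone, median -0.13, adjusted p = 0.00317, and adjusted p = 0.260 with an estimated correlation).

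In wild-type ER vehicle cells 1043 genes were higher and 1063 lower than in vector vehicle cells, with the GC and length correction 1293 and 1220, and centred on the fitted curve 1269 and 1183. Higher ones numbered 547 and 516 without vector vehicle replicates 1 and 2, and lower ones 454 and 479 without those and 512 without wild-type ER vehicle replicate 2. The hairpin and the construct changed together here, so their parts cannot be read from this comparison.

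**Figure D3:**
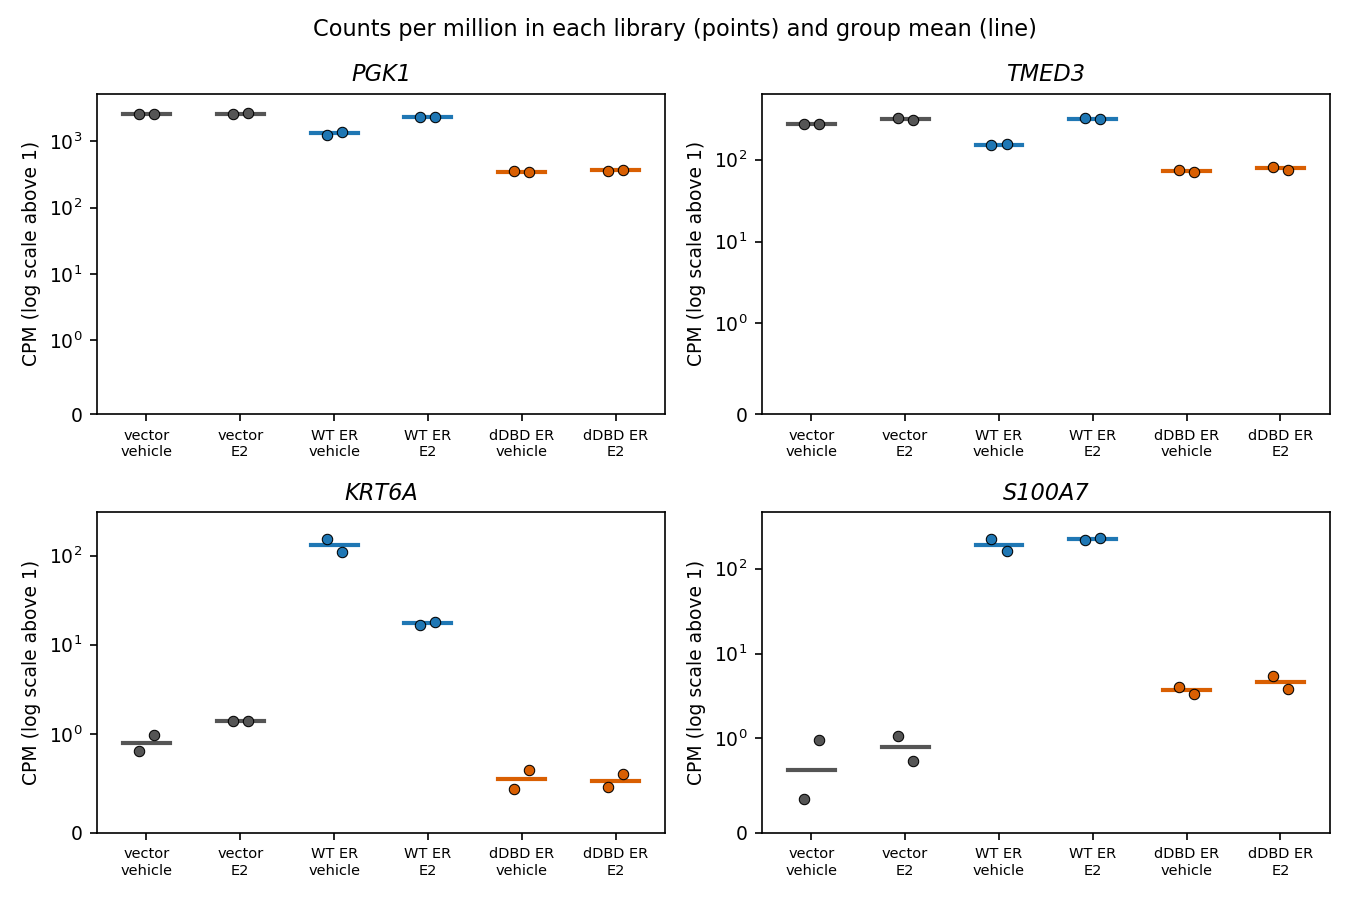
Points give the CPM of PGK1, TMED3, KRT6A and S100A7 in each of the 12 libraries and lines the mean of the 2 libraries of a condition, on an axis that is logarithmic above 1 and linear below it. PGK1 is lowest in dDBD ER libraries (349 CPM with vehicle), and KRT6A and S100A7 are highest in wild-type ER libraries, where KRT6A falls from 131 to 17.3 CPM with E2.

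dDBD ER cells without E2 had little PGK1, at 349 ± 2.01 CPM against 2547 ± 20.9 CPM in vector cells, a 7.31-fold lower level (-2.87, SE 0.072, adjusted p = 4.49e-24). The ER target WISP2 (-2.12), FILIP1L (-1.98), the trafficking gene TMED3 (-1.93), the collagen prolyl hydroxylase gene P4HA2 (-1.87) and the GPI-anchor gene PIGU (-1.71) were lower too, and AGR2, a disulfide isomerase of secretory cells, by -1.63. The imprinted non-coding RNA H19 rose from 9.31 ± 1.45 to 95.4 ± 2.46 CPM (3.33, SE 0.13, adjusted p = 4.14e-19). S100A8 (2.76), S100A9 (2.63), the bradykinin receptor BDKRB2 (2.52) and S100A7 (2.32) were higher, all S100 values being subject to shared reads. S100A12 had 2 counts in vector and 25 in dDBD ER vehicle libraries, a ratio of 13.99 (95% interval 3.49 to 122). SAA1 had 3 and 22 counts, a ratio of 8.20 (2.46 to 42.8), and lost its call without dDBD ER vehicle replicate 2 (2.51 in place of 2.93).

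Interferon genes were higher in dDBD ER than in vector vehicle cells in 17 of 32 cases (21 adjusted over the list alone, median 0.36, adjusted p = 8.62e-06), with IFIT2 (1.38), XAF1 (1.25), IFIT3 (1.07) and the antiviral membrane protein BST2 (0.58) among them. Of 28 p53 targets 12 were higher and 2 lower (16 and 2 adjusted over the list alone, median 0.23, adjusted p = 0.000728), CCNG1 by 1.26 and SESN2 by 0.70. Both calls held with an estimated correlation. Of 60 estrogen-induced genes 17 were lower and 7 higher (19 and 8 adjusted over the list alone, median -0.046, adjusted p = 0.0106), THBS1 by -1.26, STC2 by -1.06 and TFF1 by -0.63, and of 38 estrogen-repressed genes 17 were higher and 8 lower (18 and 9 adjusted over the list alone, median 0.23, adjusted p = 0.0106). With an estimated correlation the adjusted p of these lists were 0.284 and 0.140. G1/S genes were higher in 9 of 44 cases (15 and 2 down adjusted over the list alone, median 0.22, adjusted p = 0.00198, and adjusted p = 0.140 with an estimated correlation). Unfolded protein response genes were higher in 6 of 25 and lower in 1 (8 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.0106, and adjusted p = 0.394 with an estimated correlation). NF-kB genes were higher in 7 of 18 and lower in 1 (8 and 2 adjusted over the list alone, median 0.33, adjusted p = 0.0269), with adjusted p = 0.269 with an estimated correlation, 0.0616 without vector vehicle replicate 2 and 0.0762 without dDBD ER vehicle replicate 2. Ribosome biogenesis genes were lower in 11 of 40 and higher in 1, alike over the list alone (median -0.11, adjusted p = 0.0106), with adjusted p = 0.324 with an estimated correlation and 0.0587 without dDBD ER vehicle replicate 2. Hypoxia and glycolysis genes, 7 lower and 4 higher of 26 (7 and 5 adjusted over the list alone), passed in the downward direction (adjusted p = 0.0106) with a mean of -0.10 and a median of 0.028. That call had adjusted p = 0.205 with an estimated correlation and 0.345 with no filter on low counts.

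In all 1689 genes were higher and 1776 lower in dDBD ER than in vector vehicle cells. With the GC and length correction these were 2158 and 2108, and centred on the fitted curve 1898 and 2345 (44.7% higher in place of 48.7%). Higher ones numbered 1081 and 957 without vector vehicle replicates 1 and 2 and 1068 and 998 without dDBD ER vehicle replicates 1 and 2, and lower ones 1111, 1059, 1149 and 984.

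Between the introduced receptors, dDBD ER vehicle cells had more UPK3A (2.03), H19 (1.89, SE 0.11, adjusted p = 1.31e-14), the TGF-beta pseudoreceptor gene BAMBI (1.79) and the ATP-gated channel gene P2RX2 (1.41) than wild-type ER vehicle cells, and ESR1 was higher by 0.47 (SE 0.069, adjusted p = 9.16e-06). S100A7 (-5.69), SPRR1B (-5.36), KRT6A (-7.89), AGR2 (-1.46) and PGK1 (-1.91) were lower. KRT1, with 0 counts in dDBD ER vehicle against 222, was at least 72.2-fold lower. Of 60 estrogen-induced genes 30 were lower and 2 higher (33 and 4 adjusted over the list alone, median -0.31, adjusted p = 1.37e-20). Of 32 interferon genes 18 were higher (22 adjusted over the list alone, median 0.36, adjusted p = 2.13e-11), IFIT3 by 1.03 and IFIT1 by 0.91, and of 18 TGF-beta and mesenchymal genes 7 were lower (10 and 3 up adjusted over the list alone, median -0.38, adjusted p = 5.77e-05), the laminin gene LAMC2 by -1.39 and FN1 by -0.79. These 3 calls held with an estimated correlation. Over all genes 771 were higher and 732 lower (51.3% higher), with the GC and length correction 1061 and 1079, and with the correction centred on the fitted curve 840 and 1265 (39.9% higher). Higher ones numbered 410 without wild-type ER vehicle replicate 2 and 332 and 433 without dDBD ER vehicle replicates 1 and 2, and lower ones 371 and 432 without the latter.

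**Figure D4:**
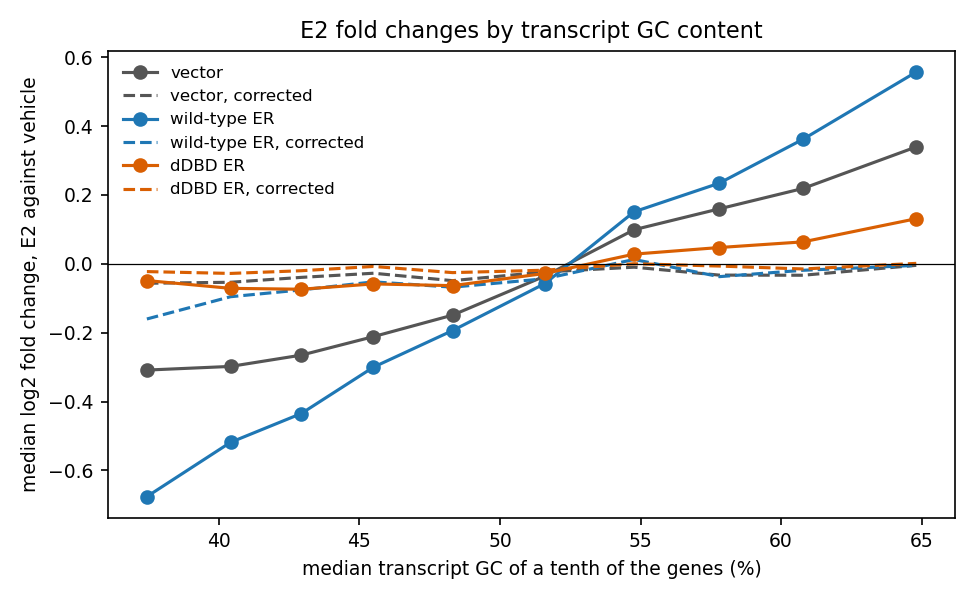
Points give the median log2 fold change between E2 and vehicle in each 10% of the tested genes ordered by transcript GC content, plotted at its median GC content in percent, and dashed lines give the same after the GC and length correction. The medians rise from -0.68 to 0.56 in wild-type ER, from -0.31 to 0.34 in vector and from -0.049 to 0.13 in dDBD ER cells.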

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

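All tests of explanations in this part were chosen after the values they concern had been seen.

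The E2 response differed between kinds of cell by the interaction test. Comparing wild-type ER with dDBD ER cells, the E2 fold change with its sign was higher for 2384 genes and lower for 2252. A lower one can be a stronger fall, as for ESR1 (-1.55 against -0.0020), which is among the genes of the second pattern below. SLC47A1 (2.14), MIR503HG (2.01) and TFF1 (0.64, and 0.24 with the GC and length correction) responded more in wild-type ER cells, and C1GALT1 (-3.01), KRT6A (-2.86), GPNMB (-2.61), DSC2 (-2.60), ESR1 (-1.54) and EFEMP1 (-1.29) lay lower there. ANKRD2 (2.37) and HBA1 (2.27) lay higher but lost the call without dDBD ER vehicle replicate 1 (1.76 and 1.85). With the GC correction centred on the fitted curve HBA1 lost it too (1.59, adjusted p = 0.0538). Lists that differed had medians of 0.29 (estrogen-induced), -0.29 (estrogen-repressed), -0.47 (mitosis), 0.56 (ribosome biogenesis) and -0.36 (p53 targets), none of them past the threshold with an estimated correlation.

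Comparing wild-type ER with vector cells, 915 genes had a higher E2 fold change, with its sign, and 520 a lower one. They are called responding more and less here, though a lower one can be a stronger fall. Without vector vehicle replicates 1 and 2 these were 504 and 531 more and 268 and 288 less, without vector E2 replicate 2 they were 468 and 253, without wild-type ER vehicle replicate 2 they were 540 and 336, and without wild-type ER E2 replicate 1 586 responded more. PLAT (-4.05), KRT6A (-3.51), DSC2 (-2.61), GREB1 (-1.19) and ESR1 (-1.003) lay lower. The other genes largest in this contrast rested on single libraries. HBA1 (2.03) lost its call without vector vehicle replicate 1 (2.01) or 2 (2.04), wild-type ER vehicle replicate 2 (1.78) or wild-type ER E2 replicate 2 (1.83). FAM229A (1.32) lost it without vector vehicle replicate 1 (1.04), vector E2 replicate 2 (1.21), wild-type ER vehicle replicate 2 (1.23) or E2 replicate 2 (1.16). TMEM38A (1.29) lost it without vector vehicle replicate 1 (1.18), vector E2 replicate 1 (1.29) or 2 (1.27), wild-type ER vehicle replicate 2 (1.19) or E2 replicate 2 (1.16). LOC101929523 (1.17) and RNU6-2 (-2.67) lost it without any 1 of the 8 vector and wild-type ER libraries, with values between 1.04 and 1.26 and between -3.10 and -2.40. The GC and length correction also ended the calls of FAM229A (0.92, adjusted p = 0.0728) and RNU6-2 (-2.51, adjusted p = 0.0532), and its version centred on the fitted curve that of HBA1 (1.69, adjusted p = 0.0532). The estrogen-induced list had a median of -0.25 and the NF-kB list of -0.31, each with adjusted p = 0.268 with an estimated correlation, and the latter with adjusted p = 0.173 without wild-type ER vehicle replicate 1.

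Comparing dDBD ER with vector cells, the E2 fold change with its sign was higher, which can be a weaker fall, for 411 genes and lower for 473. Without vector vehicle replicates 1 and 2 the former were 200 and 122, without vector E2 replicate 1 107, without dDBD ER vehicle replicates 1 and 2 150 and 180, and without dDBD ER E2 replicates 1 and 2 670 and 201. The latter were 255 and 175, 184, 203 and 255, and 284 without dDBD ER E2 replicate 2. ST8SIA4 (1.85), EFEMP1 (0.82) and ESR1 (0.54) lay higher, and LINC01016 (-3.38), GREB1 (-1.34) and TFF1 (-0.58) lower. TNFRSF11B (1.95) lost its call without vector E2 replicate 1 (1.55), ANKRD2 (-3.36) without dDBD ER vehicle replicate 1 (-2.75) and SLC47A1 (-2.35) without dDBD ER vehicle replicate 2 (-2.15). TMX3 (1.96) lost it without vector vehicle replicate 2, either vector E2 library, either dDBD ER vehicle library or dDBD ER E2 replicate 2 (1.67 to 2.07). NEK7 (1.87) lost it without vector vehicle replicate 1 or 2, vector E2 replicate 1, dDBD ER vehicle replicate 1 or E2 replicate 2 (1.53 to 1.95), and HCK (-2.32) without vector vehicle replicate 1, either vector E2 library, either dDBD ER vehicle library or dDBD ER E2 replicate 2 (-2.39 to -1.77). Fitted without the wild-type ER libraries, HCK did not pass either (-2.31). List medians were -0.57 (estrogen-induced), 0.38 (estrogen-repressed), -0.33 (ribosome biogenesis), -0.18 (G1/S), 0.29 (mitosis) and 0.22 (p53 targets). With an estimated correlation the last 3 of these lost their call (adjusted p = 0.210, 0.247 and 0.0741), and mitosis also with fry (adjusted p = 0.0652).

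The first pattern is the rise of E2 fold changes with transcript GC content. Argued against is that GC and length bias is the whole of the estrogen-induced rise, since the list's median in vector cells was 0.69 after the correction and 0.83 before it, and it still passed with an estimated correlation. Whether the trend comes from the libraries or from the transcripts stays open. The largest gap in GC slope between replicates was 0.269 of the gap between E2 and vehicle in wild-type ER cells and 0.525 of it in vector cells. In dDBD ER cells it was 2.99 times that gap, which was small there (0.046 log2 per 10 points of GC). Vehicle slopes were -0.045 and -0.103 in vector and -0.106 and -0.178 in wild-type ER cells. With E2 they were 0.188 and 0.079, and 0.171 and 0.268. The slopes of E2 and vehicle libraries thus did not overlap in these cells, but library preparation and treatment cannot be told apart here. A biological change in GC-rich against GC-poor transcripts was not tested separately.

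The second pattern is that the libraries labelled wild-type ER, E2 lie near vector at genes such as ESR1, PGK1 and TMED3. An exchange with the vector E2 libraries is argued against, since S100A7 was 247 times higher in the libraries labelled wild-type ER E2. A mixture of vector cells into these cultures stays open. The test used 167 genes called at least 2-fold higher in wild-type ER than in vector vehicle cells. None of them was called with E2 in vector or dDBD ER cells. Over these genes the best single share was 66.2% vector cells, with a misfit of 3.71 per degree of freedom. A bound of 5 was chosen after seeing the values. The misfit treats observed and predicted changes as independent, though both use the wild-type ER vehicle libraries, so a true mixture need not give 1. Single genes pull apart, with S100A7 at 191 CPM in vehicle and 225.5 with E2 where such a share would lower it, and TMED3 (316 CPM against 314 in vector E2) needing a larger one. With E2, PGK1 changed by 0.029 in vector (adjusted p = 0.760) and 0.059 in dDBD ER cells (adjusted p = 0.707), against 0.82 in wild-type ER cells. TMED3 changed by 0.20 in vector (adjusted p = 0.0161) and 0.13 in dDBD ER cells (adjusted p = 0.351), against 1.05 in wild-type ER cells. Whether E2 acts directly on such genes in wild-type ER cells is not known. A weaker effect of the hairpin or construct in the E2 than in the vehicle cultures is a candidate explanation that met its test. The bound of that test was likewise chosen after seeing the value. The sets held genes called at least 2-fold lower or higher in dDBD ER than in vector vehicle cells. None of them was called with E2 in vector or dDBD ER cells. With E2 in wild-type ER cells the set of 83 lower genes moved up on balance (median 0.365, and 0.226 with the GC and length correction, fry adjusted p = 3.58e-05). The set of 186 higher genes moved down (median -0.49, and -0.59 with the correction, fry adjusted p = 7.47e-05). A mixture would predict the same, as would any other cause of a return toward vector levels, and a fry result alone is weak evidence. The set of lower genes also held PGK1, which had shown the pattern, so the result favours no explanation. An E2 response particular to wild-type ER cells, the biological explanation the design gives, stays open as untested.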

How the results depend on the processing

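The GC and length corrections and the fits without the wild-type ER libraries were chosen after seeing the data. Of 414 values of named genes, 310 kept their direction and their side of the threshold in every alternative run, and of 8114 such runs 7734 were the same, 355 lost and 17 gained a call and 8 reversed. Of 49 list calls 16 held throughout, 33 were lost with an estimated correlation, and the 4 medians of the vector-chosen sets kept their direction and call in all 72 runs. Of 18 counts of genes, 2 stayed within 1.5 times in every run and 66 of 356 alternative counts moved further. DESeq2 size factors, both filters and the construct-only fits moved no count that far. Replicate numbers did not pair the libraries (correlations of deviations from -0.117 to 0.207, 1 of 15 over 0.1). A replicate block moved no count by over 1.5 times (2971 raised genes in vector cells) and ended no call of a named gene or list, though 2918 of the 2930 raised and 2662 of the 2684 lowered genes in vector cells kept theirs, and it added calls for 4 named genes such as IFIT3 in dDBD ER cells (0.41). With the DESeq2 Wald test the counts that moved were 1694 lowered in vector and 95 in dDBD ER cells, 1431 lower in wild-type against dDBD ER responses, 269 lower against vector, 187 higher for dDBD ER against vector, 536 higher in wild-type ER and 1064 in dDBD ER vehicle cells, and 491 higher and 486 lower between these. The GC and length correction gave 349 lowered genes in dDBD ER cells and, centred on the fitted curve, 369 there, 1526 higher in wild-type against dDBD ER responses and 1265 lower in dDBD against wild-type ER vehicle cells. Without the wild-type ER libraries 310 fell in dDBD ER cells. The cause was not tested. Leaving out 1 library gave 1950 to 3032 raised and 1608 to 3110 lowered genes in vector, 3173 to 3946 and 3379 to 4489 in wild-type ER and 27 to 786 and 3 to 236 in dDBD ER cells. For differences of response it gave 1781 to 2422 and 1656 to 2499 (wild-type minus dDBD ER), 468 to 1194 and 253 to 665 (wild-type ER minus vector), and 107 to 670 and 175 to 627 (dDBD ER minus vector). In vehicle it gave 516 to 1178 and 454 to 1131 (wild-type ER against vector), 957 to 1849 and 984 to 1866 (dDBD ER against vector), and 332 to 841 and 371 to 802 (dDBD against wild-type ER). Reversed were S100A7 with E2 in wild-type ER cells (0.24, to -0.019 and -0.074 with the GC corrections) and ESR1 with E2 in dDBD ER cells (-0.0020, to 0.083 and 0.067 with the GC corrections, 0.015 with size factors and with the Wald test, 0.010 with no filter, and 0.057 without dDBD ER vehicle replicate 2, against -0.058 without replicate 1). Low counts limit genes near 1 CPM, where 3 counts are 0.228 to 0.377 CPM.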

Other observations

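The tests of explanations in this part were chosen after the pattern had been seen.

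Several genes of squamous differentiation and skin inflammation were higher in wild-type ER than in vector and dDBD ER vehicle cells. They were gathered after the data were seen, largely because they were high in wild-type ER vehicle libraries, so their number and median there are no test of a squamous program. Squamous genes that were looked up and found at few or 0 counts include KRT5, KRT14, TP63 and DSG3. KRT16, a keratin of activated epidermis, was at 4.39 ± 0.178 CPM in vector, 158 ± 44.1 in wild-type ER and 8.47 ± 0.932 in dDBD ER vehicle libraries, and the lipocalin gene LCN2 at 83.9 ± 1.13, 470.1 ± 112 and 274 ± 14.01 CPM. Of the 14 genes tested, 6 were also higher in dDBD ER than in vector vehicle libraries and 0 lower. With E2, 10 of the 14 fell in wild-type ER cells and 1 rose (median -0.57), with the limit that high levels in the same vehicle libraries had led to their choice. KRT16, KRT17 and IVL did not pass, but fell after the GC and length correction (-0.64, -0.70 and -0.69). Among those that fell were KRT10 (-2.14, adjusted p = 1.19e-17), KRT6B (-1.85) and SPRR1B (-0.99). The 1 that rose, S100A7 (0.24, adjusted p = 0.0419), had -0.019 after the GC and length correction and -0.074 with the correction centred on the fitted curve. It also lost its call with the DESeq2 Wald test (0.26) and without vector E2 replicate 1 (0.20) or 2 (0.20), wild-type ER vehicle replicate 2 (0.019), wild-type ER E2 replicate 1 (0.24) or 2 (0.16), dDBD ER vehicle replicate 1 or 2 (0.24 each) or dDBD ER E2 replicate 1 (0.20).

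Basal keratinocytes or their RNA in the wild-type ER cultures are argued against as a source, because KRT5 and KRT14, abundant keratins of basal keratinocytes, together had 11 counts in the 4 wild-type ER libraries against 5302 for KRT6A, KRT6B and KRT6C, which is 0.207%. Basal keratins cannot decide on differentiated keratinocytes, so such cells or their RNA stay open as a source. Of the basal marker TP63, 6 counts were seen in wild-type ER vehicle and 3 in vector vehicle libraries. The hairpin alone, acting alike in both cells that carry it, is argued against for these genes, since their median difference from vector in dDBD ER vehicle cells was 0.146 of that in wild-type ER vehicle cells. The choice of genes favours a low ratio. In the direct comparison 14 of the 14 were lower in dDBD ER than in wild-type ER vehicle cells, S100A7 by -5.69 (SE 0.16, adjusted p = 1.44e-22), but they are the same chosen genes. A part for the hairpin stays open where dDBD ER cells also exceeded vector cells. There S100A9 was higher by 2.63 against 4.32 in wild-type ER cells, S100A8 by 2.76 against 5.79, LCN2 by 1.71 against 2.49 and KRT17 by 1.23 against 2.26. An effect of the introduced wild-type receptor may account for these levels, and so may a difference between these cultures that arose before treatment. With 1 construct per receptor form in these labels, neither was tested.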
